A study of Amphiprion ocellaris with 20 samples.

How the data were processed

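RNA was taken from entire Amphiprion ocellaris larvae kept in beakers of sea water, and stranded libraries were made from poly-A RNA, per the labels' protocols. The submitters' processing notes name fastp 0.23.2, a read trimmer, and Salmon 1.7.0, which estimates transcript abundance from reads. The genome build and the annotation are not given in the sources used here. The authors deposited a table of the whole series, with 24310 rows of Ensembl gene identifiers.

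Samples were grouped by their titles and treatment labels into 10 DMSO and 10 T3 samples. All 20 columns of per-sample values in the deposited table were left out, because no label holds any of their names. The RefSeq gene table used here fills in an Ensembl identifier for 0 of its 28286 genes, so the identifiers were not paired with gene symbols. This is a limit of that reference table and not of the deposited identifiers. The planned model of T3 against DMSO, its gene list tests and all of its alternatives were not run. No fold change, error or p-value was therefore computed. Depth was not computed either, because the columns of values were left out.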

Results

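Whole larvae of the clownfish Amphiprion ocellaris were profiled by poly-A RNA sequencing 2 days after treatment. The series has 20 samples. The labels place 10 of them in a group given the solvent dimethyl sulfoxide (DMSO) at 0.0001%. The other 10 are in a group given T3 at 1e-07 M, for which no DMSO percentage is recorded. T3 (triiodothyronine) is the form of thyroid hormone that binds the nuclear thyroid hormone receptors with the higher affinity. The comparison the design implies asks how gene expression in T3-treated larvae differed from that in DMSO-treated larvae.

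No value for that comparison is reported. The deposited table has 20 columns of per-sample values, and 0 of their names occur in the labels of any sample. The sample labels and the record of the series were the only sources searched for a key from column names to samples, and neither held a column name. Neither the position of a column nor its values was used to assign it. No depth, fold change, test or count of changed genes is therefore given for either group.

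The table has 24310 gene identifiers in the Ensembl format. The RefSeq gene table used here gives an Ensembl identifier for 0 of its 28286 genes, so it could not pair these identifiers with symbols. The gene lists fixed before the data were examined, among them thyroid hormone receptors, deiodinases, pigment cell genes and opsins, were not analysed here.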

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

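None of the alternatives planned for T3 against DMSO was run, because no column of the table was tied to a sample and so there was no expression result to recompute. After the table was seen, only the matching of column names was repeated with looser rules. With separators and leading zeros ignored, 0 of the 20 column names occurred in a label. By the final number alone, 10 columns shared their number with the titles of 2 samples, a DMSO and a T3 sample. The other 10 shared it with none. The titles of both groups carry the same numbers, so this rule could not have matched a column to a single sample. No paired analysis was possible because no column was tied to a treated or a control sample.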
